A study of Homo sapiens with 14 samples.

How the data were processed

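RNA-seq of the human breast cancer line MCF-7 was taken from 1 deposited series of 14 libraries. Per the labels, mock-nucleofected cells received DMSO, GDC-9545 at 100 nM or GDC-0927 at 100 nM and carry a time of 48 h, and other cells received a non-targeting siRNA (NTC) or an siRNA against ER (siER) and carry 48 h or 72 h. Each of these 7 groups held 2 libraries from duplicates. Whether duplicates are separate cultures, and whether groups were run side by side, is not stated. Per the submitters' protocol text RNA was extracted with a column kit, and libraries were made with 2 Illumina kits, TruSeq RNA v2 and TruSeq Stranded Total RNA, without saying which library used which.

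The deposited table holds raw read counts per Ensembl gene. Per the submitters' processing notes reads were aligned with GSNAP to GRCh38, and no version is stated. The counting tool and annotation used by the authors are not given in the sources used here. The table had 58302 genes, all values were whole numbers, and each column matched 1 library. Symbols were found for 41836 of the identifiers, and 58039 were in GENCODE release 29, from which coordinates, strands and opposite-strand overlaps were read. A gene was given as uncertain for overlap where a gene on the opposite strand held at least 0.1 of its counts. Library totals ran from 24.6 to 94.7 M counts (M, 1e6), and each is given in the report.

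Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr over the groups, which left 18918 genes holding at least 99.95% of the counts of each library. Libraries were scaled by TMM, with factors from 0.988 to 1.02. A quasi-likelihood model with a term for each group was fitted to all 14 libraries, with a common dispersion of 0.0037, 7 residual degrees of freedom and 10.8 prior degrees of freedom. P-values were adjusted by Benjamini-Hochberg over all tested genes within a comparison, and genes under 0.05 were called changed. The standard error of a log2 fold change was its size divided by the root of its F value. Log CPM for components and correlations used a prior count of 2.

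The comparisons were GDC-9545 with DMSO, GDC-0927 with DMSO, GDC-9545 with GDC-0927, siER with NTC at 48 h and at 72 h, the difference of the siER effects at 72 h and 48 h, the difference of the siER effect at 48 h from each compound's effect, NTC at 48 h with DMSO, and NTC at 72 h with NTC at 48 h. Differences of effects were tested as contrasts of contrasts in the same model. Overlaps of called genes were compared with the number expected from the sizes of the sets, and for the compounds, which share the DMSO libraries, with 20 simulated sets in which no gene changed.

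There were 25 gene lists, of which 24 had at least 5 measured members and were tested: estrogen-induced genes, estrogen-repressed genes, luminal epithelial identity, nuclear receptors and coregulators, DNA replication and E2F targets, G2/M and mitosis, cyclins, CDKs and CDK inhibitors of G1, BCL2 family, p53 targets, interferon-stimulated genes, NF-kB and inflammatory cytokines, cholesterol synthesis and uptake, unfolded protein and integrated stress response, hypoxia and glycolysis, NRF2 targets, aryl hydrocarbon receptor targets, MAPK output and immediate early genes, growth factor receptors and ligands, ribosome biogenesis and MYC targets, lysosome, basal epithelial markers, mesenchymal and fibroblast markers, mitochondrially encoded genes, and RNAs without a poly(A) tail. Blood and immune cell markers had 4 measured members and were counted only. Lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 24 lists of a comparison, and again with the correlation estimated from the data and with fry. Members called are given over all genes and adjusted over the list alone.

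Genes are named by a rule. ESR1 is named everywhere. The largest rises and falls are named, 8 each way where a treatment is compared with its control and 5 each way elsewhere, among called genes with a mean of at least 5 CPM and no overlap between the libraries of both groups, leaving out placeholder and antisense symbols. A fixed set of 16 ER and cell cycle genes is named in the comparisons of a treatment with its control, and up to 4 called members with the largest change are named per list. Any gene outside this rule is said to have been chosen after its values were seen.

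The model was tested on simulated data made from these counts with 50 genes changed at each fold. The changed genes were drawn from those with a mean over 1 CPM, so recovery among lower genes was not measured. All other genes were left unchanged, unlike in comparisons where a large share of genes was called. For siER at 48 h it recovered 12% of genes changed 1.25-fold, 80% of those changed 1.5-fold and 100% of those changed 2-fold, with 10 false calls among 18502 genes. For the difference of siER effects it recovered 54% at 1.5-fold and 88% at 2-fold, with 5 false calls.

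The settings varied were RLE scaling, DESeq2 1.42.0, limma-voom, no count filter beyond 1 count, a filter of at least 1 CPM in at least 2 libraries, a fit of the compared groups only, a block for replicate number, leaving out each library in turn, a 2-fold minimum for shared calls, and the other list tests. Settings added after the data were seen were a fit with a trend on GC content removed per library (lowess span 0.3, 18865 genes with a GC value), thinning to equal totals, leaving out the 48 h siRNA arms, other control arms, and 72 h arms in place of 48 h arms. Replicate numbers were checked for pairing. Across 21 pairs of groups, the correlation across 11159 genes of replicate differences ran from -0.541 to 0.636, with 11 above 0.1 and 5 below -0.1, so numbers were not treated as pairs. The replicate differences followed GC content across genes, with r from -0.69 to 0.52 and an absolute r over 0.4 in 6 of 7 groups. With the GC trend removed, 6 pairs of groups lay above 0.1 and 2 below -0.1. No library was left out. Protein, splicing and sequence variants were not examined, since the deposited values are counts per gene.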

Results

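MCF-7, an estrogen receptor (ER) positive human breast cancer cell line, was profiled by RNA-seq to follow what happens when ER is lost or blocked. The labels place 14 libraries in 7 groups of 2. Mock-transfected cells received DMSO, GDC-9545 at 100 nM or GDC-0927 at 100 nM, and carry a label of 48 h that names the nucleofection. Other cells received a non-targeting siRNA (NTC) or an siRNA against ER (siER) and were taken at 48 h or 72 h. GDC-9545, also named giredestrant, is an ER antagonist and degrader, and GDC-0927 is an ER degrader given here by its code name. The length of exposure to the compounds is not stated separately. Library totals, in units of 1e6 (M), were 30.2 and 94.7 M counts with DMSO, 50.1 and 47.2 M with GDC-9545, and 41.7 and 27.8 M with GDC-0927. Totals were 24.6 and 29.1 M with NTC at 48 h, 40.9 and 46.0 M with siER at 48 h, 85.1 and 51.8 M with NTC at 72 h, and 33.2 and 47.7 M with siER at 72 h. The 10 most abundant genes took 3.44% to 4.32% of the counts of a library, and mitochondrially encoded genes took 1.48% to 2.42%. Duplicates correlated across genes at r = 0.991 to 0.997, where genes are not independent replicates. The differences that remained between duplicates followed the GC content of genes, at an absolute r over 0.4 in 6 of 7 groups.

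The labels do not say that the duplicates are separate cultures, so every p-value here measures only the spread between these samples. Each group had n = 2, levels are counts per M (CPM), and the figure in brackets after a log2 fold change is its standard error. Genes called changed had an adjusted p-value under 0.05 over 18918 tested genes. Gene lists, the rule for naming genes and the tests were fixed before the data were examined, except those said to have been added or chosen after. Which libraries are stranded is not known, since the labels name 2 kits, so a gene that overlaps another on the opposite strand is given as uncertain.

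ESR1 encodes ER alpha and is the target of both the siRNA and the compounds, so its transcript (ENSG00000091831, chromosome 6:151656691-152129619, plus strand, GENCODE release 29 on GRCh38) was read first. ESR1 stood at 306 and 315 CPM with DMSO, 385 and 418 CPM with GDC-9545, and 393 and 375 CPM with GDC-0927. ESR1 stood at 220 and 208 CPM with NTC at 48 h and at 58.6 and 53.1 CPM with siER at 48 h. At 72 h ESR1 stood at 297 and 284 CPM with NTC and at 110 and 115 CPM with siER. The siRNA left 26.1% of the control level at 48 h, a log2 fold change of -1.94 (0.07) with adjusted p = 4.31e-13. At 72 h 38.6% was left, a log2 fold change of -1.37 (0.07) with adjusted p = 2.05e-11. The compounds did not lower the transcript. ESR1 rose with GDC-9545 to 129% of the DMSO level, 0.37 (0.06) with adjusted p = 8.79e-05, and with GDC-0927 to 124%, 0.31 (0.06) with adjusted p = 0.000622. ER protein was not measured.

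**Figure D1:**
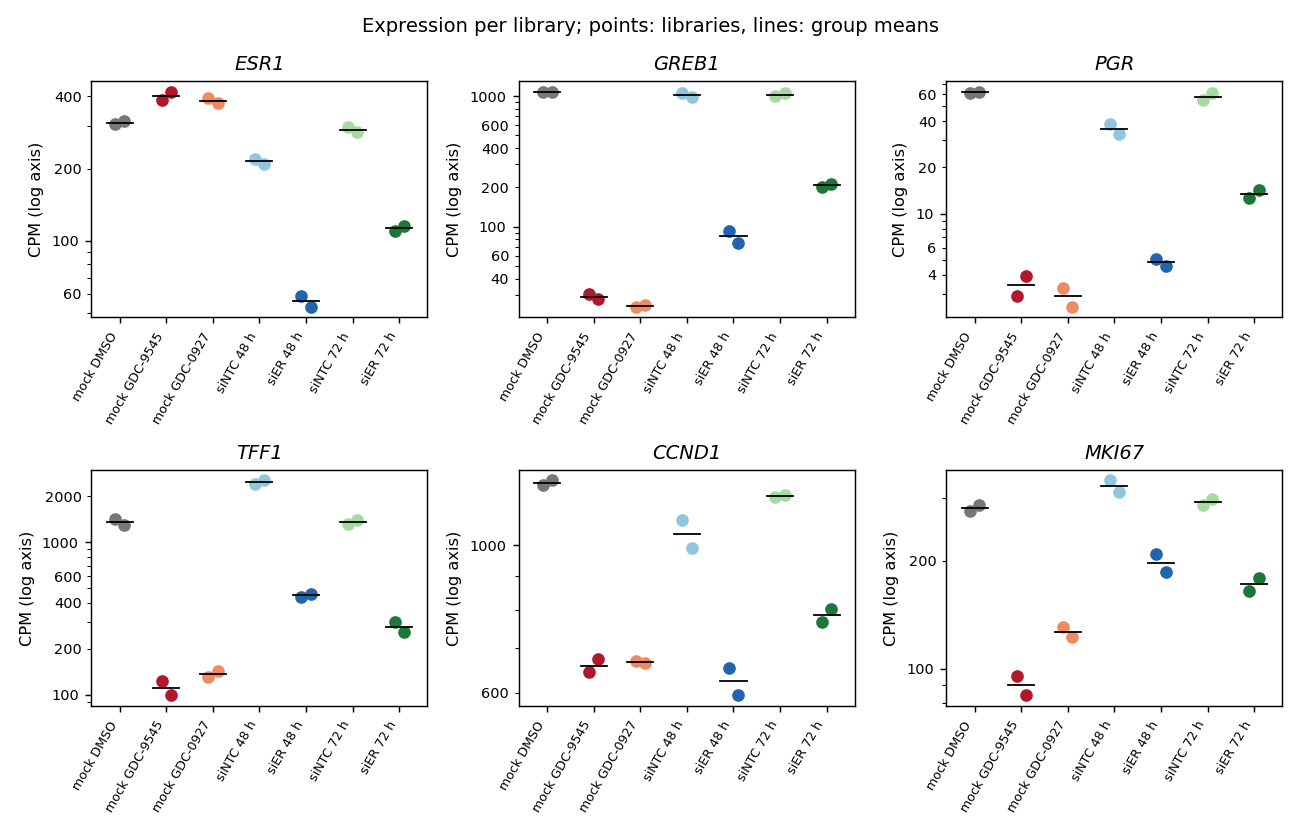
CPM on a log axis for ESR1, GREB1, PGR, TFF1, CCND1 and MKI67 in the 7 groups, with a point per library and a line at each group mean. Against its own control ESR1 fell with siER, to 55.8 CPM at 48 h and 112 CPM at 72 h, and not with the compounds, while GREB1 fell in all 4 treated groups.

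Principal components were computed across the 14 libraries to see which groups lay together. The first component held 51.1% of the variance and the second 16.4%. Both compounds lay at 42.4 to 50.9 on the first component, and DMSO and the 72 h NTC libraries lay together at -51.0 to -46.9. The siER libraries lay between, at 24.0 to 28.7 at 48 h and 18.5 to 21.9 at 72 h. On the second component the 4 siRNA libraries of 48 h stood apart at -38.4 to -29.4, while DMSO and the 72 h NTC libraries lay at 15.1 to 20.8.

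**Figure D2:**
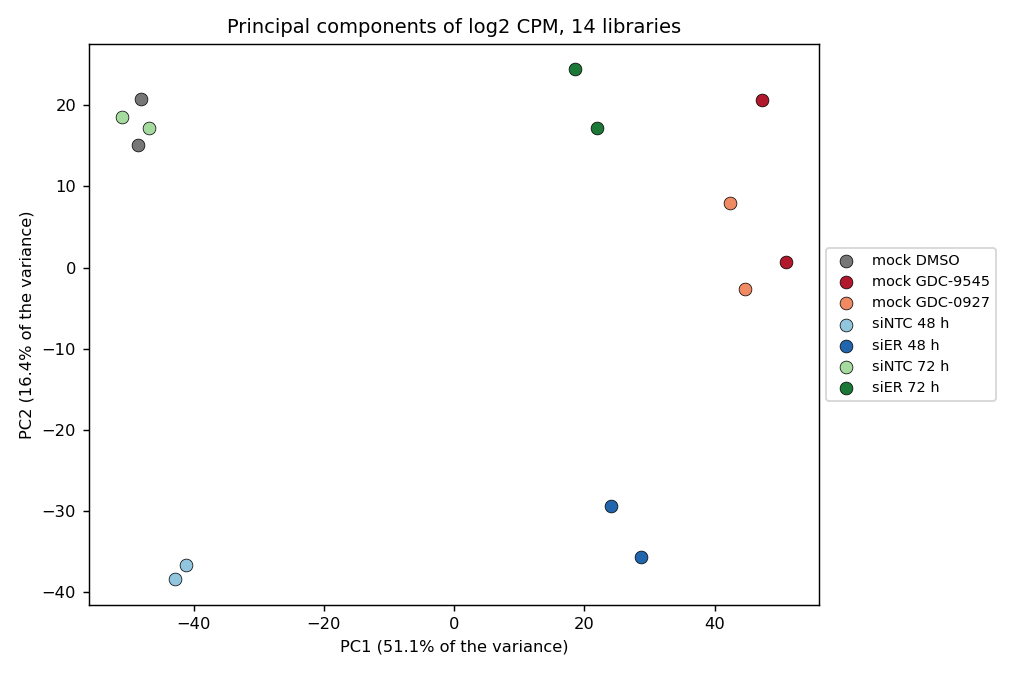
First against second principal component of log2 CPM, with a point per library coloured by group. The first component (51.1%) sets compound and siER libraries apart from controls and the second (16.4%) sets the 48 h siRNA libraries apart.

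GDC-9545 was compared with DMSO to ask what the compound does to transcription. GREB1, an ER-induced gene needed for estrogen-driven growth (ENSG00000196208, chromosome 2:11482341-11642788, plus strand), fell from 1080 to 29.1 CPM, -5.21 (0.09) with adjusted p = 2.06e-17. PGR, the progesterone receptor gene and a clinical readout of ER activity (ENSG00000082175, chromosome 11:101029624-101130524, minus strand), fell from 61.7 to 3.44 CPM, -4.17 (0.13). TFF1 (ENSG00000160182, chromosome 21:42362282-42366594, minus strand), a secreted peptide long used as an estrogen marker, fell from 1360 to 111 CPM. Genes for proliferation fell with them, with MKI67 at -1.64 on the log2 scale, while genes that ER holds down rose. In total 9746 genes changed, 4914 up and 4832 down, which is 51.5% of those tested, and 2366 of them changed 2-fold or more. The fold changes correlated with GC content across genes at r = 0.28, and 88.3% of the calls were kept in the same direction with the GC trend removed.

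Estrogen-induced genes fell almost as a whole with GDC-9545, with 43 of 44 measured members lower and 1 higher, and the same 43 and 1 when adjusted over the list alone. Their median log2 fold change was -1.83, with adjusted p = 3.67e-06 with an estimated correlation. The member that rose was ABCA3 (0.27), chosen after its values were seen. Outside the list IGSF1 fell by 6.31 (0.10) from 136 to 1.7 CPM, and inside it PDZK1 (ENSG00000174827), a scaffold protein gene, fell by 6.15 (0.22) from 18.3 to 0.258 CPM. PDZK1 held only 5 and 20 counts in the GDC-9545 libraries, so the size of its fall is uncertain. Other large falls were those of CDH26 (-6.23), RAMP3 (-4.55), MGP (-4.48), NPY1R (-4.37) and CALCR (-4.23). CXCL12, a chemokine gene, fell from 80.3 to 6.81 CPM, and CCND1, the cyclin D1 gene that ER drives to push cells through G1, fell from 1240 to 660 CPM. MYC and BCL2 also fell, to -1.22 and -1.42. Estrogen-repressed genes rose in 15 of 15 members, median 1.48 (adjusted p = 0.000603 with an estimated correlation), among them the cell death genes BMF (2.41) and BIK (2.30), and all 15 rose adjusted over the list alone.

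The largest rises with GDC-9545 were those of ACHE (ENSG00000087085, chromosome 7:100889994-100896974, minus strand), which went from 3.38 to 64.6 CPM, 4.27 (0.11) with adjusted p = 1.17e-15, and of MUC3A (4.26), a mucin gene with close paralogs and so uncertain. IL1R1, the interleukin-1 receptor gene, rose by 3.94 (0.11) from 4.37 to 67.1 CPM, and APOD, a lipocalin gene, rose by 3.48 from 59.3 to 662 CPM. ST6GAL1 (3.67), ATP6V0A4 (3.65) and UPK3A (3.45) also rose, as did GABBR2 (3.84), which overlaps a pseudogene on the opposite strand and is uncertain. The luminal factors FOXA1 and GATA3 rose by 0.58 and 0.50. CDKN1A, a CDK inhibitor gene, rose by 0.85, and CCNG2, a cyclin gene tied to arrest that ER represses, rose by 1.01. ERBB2 rose by 1.15, with MIEN1 overlapping on the opposite strand, so this value is uncertain.

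DNA replication and E2F targets fell in 43 of 43 members with GDC-9545, also 43 adjusted over the list alone, with median -1.69 and adjusted p = 6.02e-05 with an estimated correlation. ORC1, which licenses replication origins, fell by 2.44 from 43.2 to 7.95 CPM, and DSCC1 (-2.42), PRIM1 (-2.39), MCM10 (-2.36) and E2F1 (-1.70) fell too. G2/M and mitosis genes fell in 32 of 32 members, 32 adjusted over the list alone, with median -1.74 and adjusted p = 0.000684 with an estimated correlation. CDK1, the kinase that starts mitosis, fell by 2.07 from 143 to 34 CPM, beside ASPM (-2.01), DLGAP5 (-1.96) and TOP2A (-1.86). Ribosome biogenesis and MYC targets fell in 20 of 21 members, 21 adjusted over the list alone, median -0.72 (adjusted p = 0.012 with an estimated correlation), with LYAR at -1.48 and NOLC1 at -0.97. Cholesterol synthesis and uptake genes fell in 15 of 23 members and rose in 2, as they did adjusted over the list alone, median -0.56 (adjusted p = 0.0126 with an estimated correlation). Examples were STARD4 (-1.03), EBP (-1.03) and MSMO1 (-0.84).

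Several lists passed with GDC-9545 only at the preset correlation. Luminal epithelial identity genes rose in 15 of 20 members and fell in 2, the same adjusted over the list alone, median 0.48 (adjusted p = 0.156 with an estimated correlation), with SPDEF at 1.10, ELF3 at 1.05 and AGR2, an ER-induced disulfide isomerase gene, at -1.80. Nuclear receptors and coregulators rose in 27 of 34 members and fell in 3 (adjusted p = 0.171 with an estimated correlation), with GPER1 at 1.22. BCL2 family genes rose in 8 of 15 members and fell in 4 (adjusted p = 0.0801 with an estimated correlation), with BAK1 at 2.0 and PMAIP1 at -1.79. The p53 targets rose in 10 of 20 members and fell in 3 (adjusted p = 0.0765 with an estimated correlation), with BTG2 at 1.49. NF-kB and inflammatory cytokine genes rose in 5 of 10 members (adjusted p = 0.171 with an estimated correlation), with RELB at 1.32. Unfolded protein and integrated stress response genes fell in 11 of 24 members and rose in 4 (adjusted p = 0.171 with an estimated correlation), with XBP1, an ER-induced stress factor gene, at -1.43. Aryl hydrocarbon receptor targets rose in 4 of 6 members and fell in 2 (adjusted p = 0.156 with an estimated correlation), with AHRR at 3.36 and CYP1A1 at 2.50.

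The other lists did not pass with GDC-9545, though members moved. Interferon-stimulated genes fell in 11 of 25 members and rose in 5, median -0.16 with adjusted p = 0.0831. Cyclins, CDKs and CDK inhibitors of G1 rose in 6 of 17 members and fell in 8 with adjusted p = 0.601, and their median (-0.03) and mean (0.04) had opposite signs. CDKN2B rose by 2.70 and CDK6 by 1.88, while CDC25A fell by 2.05. Hypoxia and glycolysis genes rose in 8 of 21 members and fell in 7 (adjusted p = 0.937), NRF2 targets rose in 2 of 16 and fell in 8 (adjusted p = 0.374), and MAPK output and immediate early genes rose in 10 of 20 and fell in 7 (adjusted p = 0.466). Growth factor receptors and ligands rose in 12 of 23 members and fell in 8 (adjusted p = 0.269), with AREG, an EGFR ligand gene that estrogen induces, at -3.59. Lysosome genes rose in 15 of 22 members and fell in 4 (adjusted p = 0.253), with the estrogen-induced protease gene CTSD at -2.13. Basal epithelial markers rose in 3 of 14 members and fell in 6 (adjusted p = 0.116), with CD44 at -1.96, and mesenchymal and fibroblast markers rose in 4 of 13 and fell in 2 (adjusted p = 0.314). Mitochondrially encoded genes rose in 8 of 13 members (adjusted p = 0.0728), and RNAs without a poly(A) tail rose in 11 of 21 and fell in 3 (adjusted p = 0.129). Of the blood and immune cell markers 4 were measured, too few to test, and 3 rose from low levels.

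GDC-0927 was compared with DMSO to ask the same of the other compound. Many of its largest changes were in the same genes. GREB1 fell to 24.8 CPM, -5.44 (0.10), PGR fell to 2.89 CPM, -4.39, and PDZK1 fell to 0.377 CPM, -5.58, at only 16 and 10 counts. ACHE rose by 3.83, IL1R1 by 3.58 and APOD by 3.26. In total 9330 genes changed, 4641 up and 4689 down, which is 49.3% of those tested, and 2065 changed 2-fold or more. These fold changes correlated with GC content across genes at r = 0.35, and 82.7% of the calls were kept in the same direction with the GC trend removed.

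Estrogen-induced genes fell in 42 of 44 members with GDC-0927 and rose in 1, as they did adjusted over the list alone, median -1.60 (adjusted p = 1.09e-05 with an estimated correlation). IGSF1 (-5.81), CDH26 (-4.72), ATRNL1 (-4.59), CALCR (-4.49) and RAMP3 (-4.45) fell most beside those named, and TFF1 (-3.31), CXCL12 (-3.48), CCND1 (-0.89), MYC (-0.96) and BCL2 (-1.26) fell too. Estrogen-repressed genes rose in 15 of 15 members, 15 adjusted over the list alone, median 1.40 (adjusted p = 0.000557 with an estimated correlation), with BMF at 2.57. MUC3A (3.81), GABBR2 (3.45) and PSCA (3.18) rose and are uncertain, the first by its paralogs and the other two by opposite-strand overlap, and ST6GAL1 (3.31) and ATP6V0A4 (3.21) rose as well. FOXA1 rose by 0.46, GATA3 by 0.49, CDKN1A by 0.88 and CCNG2 by 0.76, and ERBB2 by 1.06 with the overlap named above. DNA replication and E2F targets fell in 43 of 43 members, 43 adjusted over the list alone, median -1.46 (adjusted p = 7.54e-05 with an estimated correlation), with DSCC1 at -2.44, PRIM1 at -2.14 and E2F1 at -1.39. All members of the G2/M and mitosis list fell, 32 of 32, 32 adjusted over the list alone, median -1.38 (adjusted p = 0.000582 with an estimated correlation), with CENPE at -1.88, TOP2A at -1.63 and MKI67 at -1.14. Ribosome biogenesis and MYC targets fell in 19 of 21 members, 19 adjusted over the list alone, median -0.66 (adjusted p = 0.0197 with an estimated correlation).

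Cholesterol synthesis and uptake genes fell in 15 of 23 members with GDC-0927 and rose in 2, median -0.32 (adjusted p = 0.0797 with an estimated correlation). Interferon-stimulated genes rose in 17 of 25 members and fell in 4, the same adjusted over the list alone, median 0.47 (adjusted p = 0.18 with an estimated correlation). XAF1 rose by 1.04 and IFI27 by 0.88, both products of interferon signalling. Aryl hydrocarbon receptor targets rose in 4 of 6 members and fell in 2 (adjusted p = 0.129 with an estimated correlation), with AHRR at 2.99 and CYP1A1 at 2.20. Cyclins, CDKs and CDK inhibitors of G1 had a median of -0.14 and a mean of 0.03, and hypoxia and glycolysis genes a median of 0.02 and a mean of -0.03, so the signs differed.

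The compounds changed largely the same genes, with 8126 changed in the same direction by both and 9 in opposite directions. Of these 4082 rose and 4044 fell, against 1206 and 1198 expected from the sizes of the gene sets. Both comparisons use the same DMSO libraries, so part of this overlap can come from the shared controls. In 20 simulated sets with no change the mean number of shared calls was 0.05. With no gene changed hardly any call can arise, so this number does not show what the shared controls add to 8126. The fold changes of these sets still correlated across genes at r = 0.439. Simulated counts were drawn gene by gene, without the trends on GC content of the real libraries. The observed correlation across genes, which are not independent replicates, was 0.914, and the observed covariance was 0.589 against 0.0263 in simulation.

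GDC-9545 was compared with GDC-0927 at the matched dose of 100 nM and the same labelled time to ask where the compounds differ. The clearest difference was in genes that interferon induces. MX1, which blocks viral replication (ENSG00000157601, chromosome 21:41420304-41459214, plus strand), stood at 180 CPM with GDC-0927 and 103 CPM with GDC-9545, -0.80 (0.07) with adjusted p = 4.56e-06. IFIT3, which binds viral RNA complexes (ENSG00000119917, chromosome 10:89327894-89340971, plus strand), stood at 82 and 46.2 CPM, -0.83 (0.07). ESR1 did not differ, at 0.06 with a 95% interval of -0.07 to 0.20. In total 193 genes differed, 40 higher and 153 lower with GDC-9545, and 3 of them differed 2-fold or more, CDH26 (-1.51), the antisense transcript HOXB-AS1 (2.74) and the pseudogene IFITM3P6 (-1.27), named after their values were seen.

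Interferon-stimulated genes were lower with GDC-9545 than with GDC-0927 in 22 of 25 members, 23 adjusted over the list alone, median -0.56 (adjusted p = 0.000177 with an estimated correlation). OAS3 stood at 512 and 293 CPM, -0.81 (0.07), and IFI44 at 11.3 and 6.22 CPM, -0.86 (0.10), and MX2, which is not in the list, differed by -0.79. IRF7 (-0.27), IRF9 (-0.14) and XAF1 (-0.22) were not called. Against DMSO the list passed with neither compound with an estimated correlation, at medians of -0.16 and 0.47, and IFI44 and HERC5 fell with both, to -1.22 and -1.15 with GDC-9545 and to -0.36 and -0.63 with GDC-0927. G2/M and mitosis genes were lower with GDC-9545 in 10 of 32 members, 23 adjusted over the list alone, median -0.25 (adjusted p = 0.00565 with an estimated correlation), with MKI67 at 89.8 CPM against 127 CPM with GDC-0927 and UBE2C at -0.45. DNA replication and E2F targets were lower in 7 of 43 members, 30 adjusted over the list alone, median -0.24 (adjusted p = 0.00177 with an estimated correlation), with CLSPN at -0.43 and TK1 at -0.39. Cholesterol synthesis and uptake genes were lower in 4 of 23, 10 adjusted over the list alone, median -0.17 (adjusted p = 0.00177 with an estimated correlation), among them FDPS (-0.37), EBP (-0.34) and FDFT1 (-0.29). NRF2 targets were lower in 1 of 16, the gene G6PD (-0.34), and in 6 adjusted over the list alone (adjusted p = 0.0217 with an estimated correlation), and basal epithelial markers were lower in 2 of 14, ACTG2 (-0.56) and CD44 (-0.33), and in 4 adjusted over the list alone (adjusted p = 0.0233 with an estimated correlation).

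Estrogen-induced genes were lower with GDC-9545 in 2 of 44 members, CA12 (-0.40) and CCN5 (-0.36), and in 10 adjusted over the list alone, median -0.09 (adjusted p = 0.0886 with an estimated correlation). Estrogen-repressed genes had 0 called, 2 higher adjusted over the list alone, median 0.11 (adjusted p = 0.0889 with an estimated correlation). The genes highest with GDC-9545 were SELENOP (0.74), a selenium transport gene, and KLF2 (0.60), with SERHL2 (0.74), PRICKLE1 (0.65) and GPR37L1 (0.60), which overlap other genes on the opposite strand and are uncertain. For 15094 genes, 79.8% of those tested, the 95% interval of the difference lay within 2-fold, and for 12380 it lay within 1.5-fold. The count of 193 moved to 776 without GDC-9545 replicate 1, to 65 without GDC-9545 replicate 2, to 35 without GDC-0927 replicate 1 and to 43 without GDC-0927 replicate 2. It was 373 with DESeq2 and 32 when only these 4 libraries were fitted. In the deposited column names both GDC-0927 libraries share a mark that no other group holds, as do both siER 72 h libraries, and its meaning is not given. SELENOP was not called without GDC-9545 replicate 2 (0.61), GDC-0927 replicate 1 (0.61) or GDC-0927 replicate 2 (0.86), and PRICKLE1 without the same libraries (0.58, 0.57 and 0.74). KLF2 was not called without any one of the 4 libraries (0.54, 0.67, 0.52 and 0.68), and SERHL2 without GDC-0927 replicate 1 (0.66) or 2 (0.82).

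**Figure D3:**
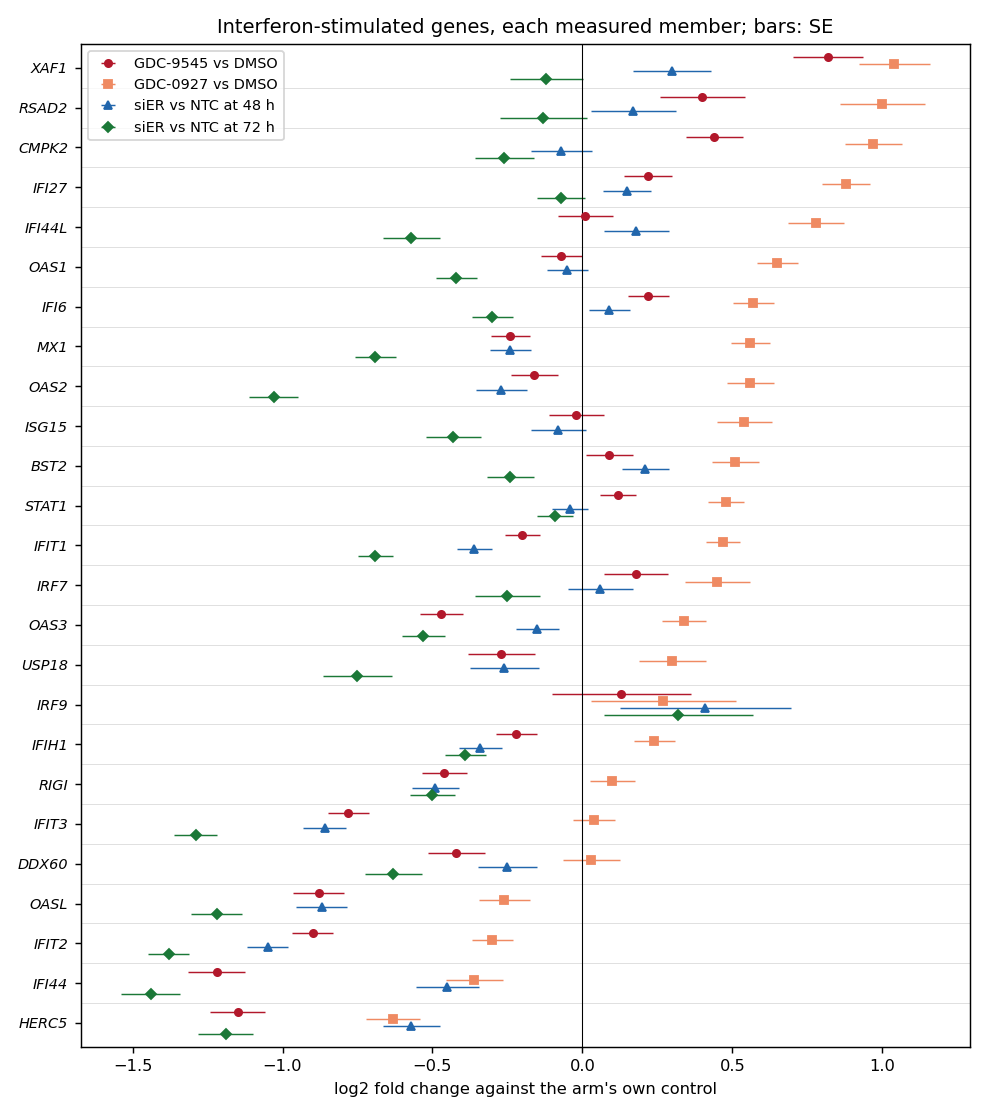
Log2 fold change of 25 interferon-stimulated genes against each arm's own control, with GDC-9545, GDC-0927 and siER at 48 h and 72 h as points and bars of 1 standard error. GDC-0927 lay above GDC-9545, with a median difference of -0.56 for GDC-9545 minus GDC-0927.

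Knockdown of ER at 48 h was compared with NTC at 48 h to ask what lowering of the transcript does without either compound. GREB1 fell to a log2 fold change of -3.60 (0.09), PGR to -2.89 (0.13) and TFF1 to -2.47, the same markers that fell with the compounds. IL1R1 rose by 3.05 (0.13) from 3.16 to 26.4 CPM and ATP6V0A4, a proton pump subunit gene, by 3.41. Proliferation genes fell less than with the compounds, with MKI67 at -0.71. In total 6583 genes changed, 3127 up and 3456 down, which is 34.8% of those tested, and 1100 changed 2-fold or more.

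Estrogen-induced genes fell in 43 of 44 members with siER at 48 h, 43 adjusted over the list alone, median -1.36 (adjusted p = 4.57e-06 with an estimated correlation). In and outside the list PDZK1 (-3.80), IGSF1 (-3.71), CDH26 (-3.65), CALCR (-3.09), NPY1R (-2.69) and CXCL12 (-2.48) fell, as did C5AR2 (-2.87) and EGR3 (-2.79), the latter uncertain for an opposite-strand overlap. CCND1 (-0.74), MYC (-1.03) and BCL2 (-0.76) fell as well. Estrogen-repressed genes rose in 15 of 15 members, 15 adjusted over the list alone, median 1.06 (adjusted p = 6.86e-05 with an estimated correlation), with BMF at 1.95 and YPEL3 at 1.59. CDH5 (2.92), APOD (2.76), CSTA (2.70) and ACHE (2.70) rose, as did MUC3A (2.79) and PSCA (2.69) with the limits given above. FOXA1 rose by 0.32, GATA3 by 0.48, CDKN1A by 0.38, CCNG2 by 1.06 and ERBB2, uncertain, by 0.82. DNA replication and E2F targets fell in 43 of 43 members, 43 adjusted over the list alone, median -0.81 (adjusted p = 0.000117 with an estimated correlation), with ORC1 at -1.23 and E2F1 at -0.73. The G2/M and mitosis list fell in 32 of 32, 32 adjusted over the list alone, median -0.69 (adjusted p = 0.00377 with an estimated correlation), with BUB1B at -0.87 and TOP2A at -0.75.

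Ribosome biogenesis and MYC targets fell in 20 of 21 members with siER at 48 h, median -0.63 (adjusted p = 0.00377 with an estimated correlation), with LYAR at -1.07 and NOP56 at -0.84. Unfolded protein and integrated stress response genes fell in 11 of 24 and rose in 1, DDIT4 (0.22), median -0.34 (adjusted p = 0.0453 with an estimated correlation), with XBP1 at -1.33 and the chaperone gene HSP90B1 at -0.82. Cholesterol synthesis and uptake genes fell in 10 of 23 and rose in 1, TM7SF2 (0.55), median -0.20 (adjusted p = 0.0453 with an estimated correlation). Interferon-stimulated genes fell in 10 of 25 and rose in 1, BST2 (0.21), and fell in 11 adjusted over the list alone, median -0.15 (adjusted p = 0.274 with an estimated correlation). NF-kB and inflammatory cytokine genes fell in 5 of 10 and rose in 1, NFKBIA (0.29), with adjusted p = 0.188, and BIRC3 stood at -1.15. Basal epithelial markers fell in 6 of 14 and rose in 2 (adjusted p = 0.0658 with an estimated correlation), with CD44 at -1.75. Growth factor receptors and ligands had a median of 0.13 and a mean of -0.05 with adjusted p = 0.729, and cyclins, CDKs and CDK inhibitors of G1 a median of -0.14 and a mean of 0.05, so the signs differed.

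Knockdown at 72 h was compared with NTC at 72 h to ask whether the changes last. AREG, an estrogen-induced growth factor gene, fell from 15.5 to 3.4 CPM, a log2 fold change of -2.18 (0.13), beside GREB1 at -2.31 (0.08) and TFF1 at -2.29 (0.09). ATP6V0A4 (3.81), ST6GAL1 (3.61), ACHE (3.59) and APOD (3.41) rose most, and IL1R1 rose by 3.56 (0.10) from 4.47 to 53.1 CPM. PCSK2 rose by 3.37, with GABBR2 (3.46) and MUC3A (3.37) uncertain as before. IGSF1 (-2.73), PDZK1 (-2.29), ATRNL1 (-2.24), NPY1R (-2.15) and PGR (-2.10) fell, with EGR3 at -2.17 and uncertain. In total 7256 genes changed, 3726 up and 3530 down, which is 38.4% of those tested, and 1273 changed 2-fold or more.

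Estrogen-induced genes fell in 43 of 44 members with siER at 72 h, and adjusted over the list alone 43 fell and 1 rose, median -1.33 (adjusted p = 2.04e-05 with an estimated correlation). CXCL12 (-1.72), CCND1 (-0.60), MYC (-0.97) and BCL2 (-1.0) fell. Estrogen-repressed genes rose in 15 of 15 members, 15 adjusted over the list alone, median 1.25 (adjusted p = 0.000171 with an estimated correlation), with BMF at 2.22 and BIK at 2.06. FOXA1 rose by 0.38, GATA3 by 0.34, CDKN1A by 0.61, CCNG2 by 0.92 and ERBB2, uncertain, by 0.85. DNA replication and E2F targets fell in 43 of 43 members, 43 adjusted over the list alone, median -0.72 (adjusted p = 0.000278 with an estimated correlation), with CDC6 at -1.11 and E2F1 at -0.65. Mitosis genes of the G2/M list fell in 32 of 32, 32 adjusted over the list alone, median -0.81 (adjusted p = 0.00272 with an estimated correlation), with CENPE at -1.0, MKI67 at -0.76 and TOP2A at -0.74. Ribosome biogenesis and MYC targets fell in 18 of 21 (adjusted p = 0.0204 with an estimated correlation), and cholesterol synthesis and uptake genes fell in 18 of 23 and rose in 2 (adjusted p = 0.0085 with an estimated correlation), with INSIG1 at -0.68.

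Interferon-stimulated genes fell in 19 of 25 members with siER at 72 h, 20 adjusted over the list alone, median -0.50 (adjusted p = 0.0128 with an estimated correlation), with IFI44 at -1.44, IFIT3 at -1.29 and OASL at -1.22. Aryl hydrocarbon receptor targets rose in 4 of 6 and fell in 1, TIPARP (-0.44), median 1.95 (adjusted p = 0.0224 with an estimated correlation), with AHRR at 2.68 and CYP1A1 at 2.49. BCL2 family genes rose in 8 of 15 and fell in 3, 9 and 3 adjusted over the list alone, median 0.20 (adjusted p = 0.0298 with an estimated correlation), with BAK1 at 1.77. Mitochondrially encoded genes rose in 9 of 13 (adjusted p = 0.519 with an estimated correlation). Cyclins, CDKs and CDK inhibitors of G1 had a median of -0.04 and a mean of 0.21 with adjusted p = 0.396, so the signs differed. With siER 4856 genes changed in the same direction at both times and 25 in opposite directions, against 616 up and 645 down expected, and these comparisons share no library.

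**Figure D4:**
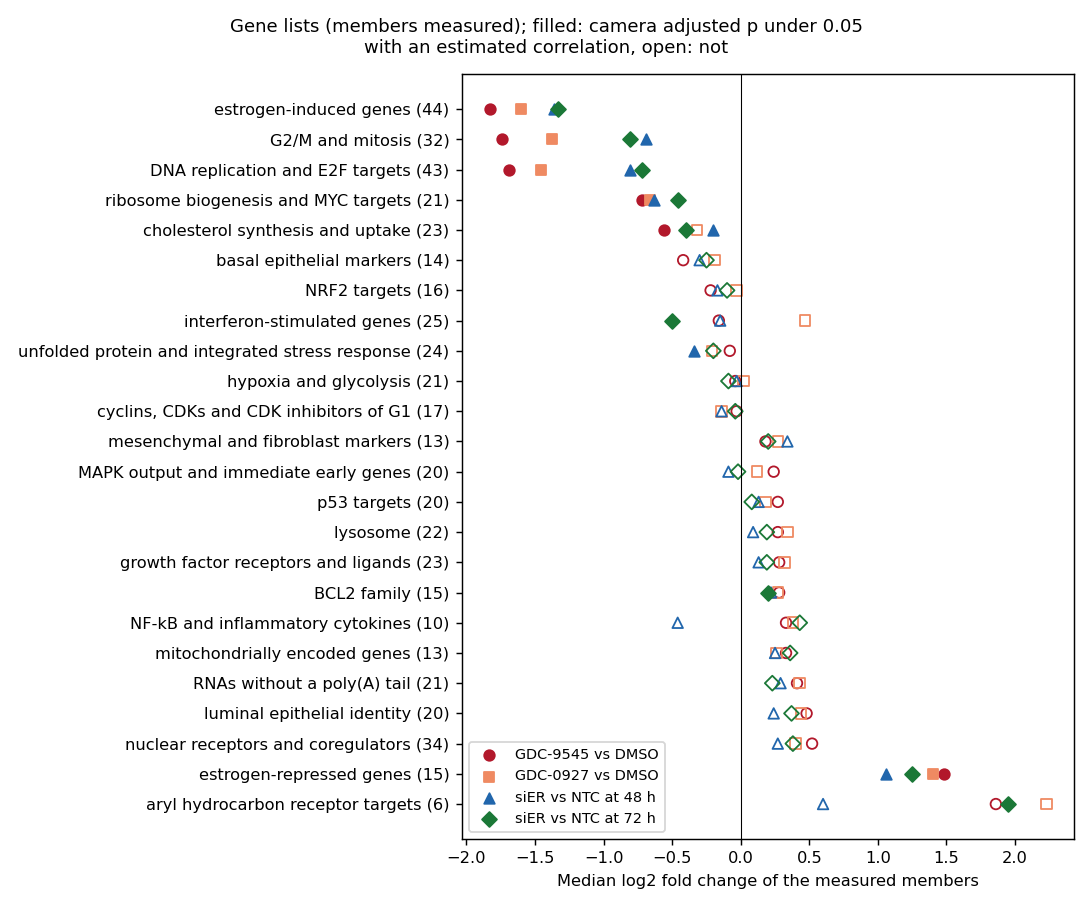
Median log2 fold change of 24 gene lists in the 4 comparisons of a treatment with its control, filled where the list passed with an estimated correlation. Estrogen-induced genes had medians of -1.83, -1.60, -1.36 and -1.33 with GDC-9545, GDC-0927, siER at 48 h and siER at 72 h.

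The siER effect at 72 h was set against that at 48 h, each from its own NTC, to ask which genes recover or drift. ESR1 was less lowered at 72 h, a difference of 0.57 (0.09) with adjusted p = 0.00308. GREB1 was less lowered by 1.29 (0.11), CDH26 by 1.57, CALCR by 1.09 (0.19), PGR by 0.79 (0.17) and CXCL12 by 0.77. PDZK1 differed by 1.51 (0.28) with adjusted p = 0.00789, and its call was lost without siER 48 h replicate 1 (1.30) and without siER 72 h replicate 2 (1.39). CYP1A1, an aryl hydrocarbon receptor target that oxidises foreign compounds (ENSG00000140465, chromosome 15:74719542-74725610, minus strand), had a siER effect larger by 1.83 (0.19) at 72 h. Its level fell with time in both arms, from 9.26 to 1.16 CPM with NTC and from 14.6 to 6.68 CPM with siER. The larger effect at 72 h thus came with a steeper fall of the control and not with a higher siER level. In total 266 genes differed, 195 higher and 71 lower at 72 h, and 61 differed 2-fold or more. The balance turned with no count filter, where 148 were higher and 213 lower. Of the 4856 genes changed in the same direction at both times 155 differed in size, 57 smaller and 98 larger at 72 h. Genes that lost their call by 72 h are not in these counts. On simulated data the test recovered 54% of 1.5-fold differences, among genes with a mean over 1 CPM. The counts therefore do not settle how general recovery was.

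Estrogen-induced genes were less lowered at 72 h in 10 of 44 members, 18 adjusted over the list alone with 1 the other way, median 0.20 (adjusted p = 0.00532 with an estimated correlation). With the GC trend removed, 23 of 44 members of this list rose in NTC from 48 h to 72 h and 5 fell, median 0.16. A rise of the control works against a smaller fall at 72 h. NF-kB and inflammatory cytokine genes were higher in the 72 h effect in 4 of 10, 7 adjusted over the list alone, median 0.50 (adjusted p = 0.0055 with an estimated correlation), namely BIRC3 (1.57), TNFAIP3 (1.07), RELB (1.03) and NFKB2 (0.51). In the NTC control itself this list had fallen in 10 of 10 members from 48 h to 72 h, median -1.14, so the difference also holds a change of the control. Aryl hydrocarbon receptor targets were higher in 2 of 6, 4 adjusted over the list alone, median 0.75 (adjusted p = 0.00607 with an estimated correlation), namely CYP1A1 and AHRR (0.83). With the GC trend removed, 3 of 6 members of this list fell in NTC from 48 h to 72 h, median -0.66. This difference therefore holds a change of the control too. Interferon-stimulated genes were lower in 6 of 25, 17 adjusted over the list alone, median -0.37 (adjusted p = 0.00604 with an estimated correlation), with IFI44 at -0.99, OAS2 at -0.76 and IFI44L at -0.75. Cholesterol synthesis and uptake genes were lower in 1 of 23, the gene INSIG1 (-0.50), median -0.11 (adjusted p = 0.0383 with an estimated correlation). With the GC trend removed, 13 of 23 members of the cholesterol list rose in NTC from 48 h to 72 h and 0 fell, median 0.14. The difference for this list thus also holds a change of the control. NUPR1 (-1.34), PTGES (-1.10), CCL5 (-1.10) and GALM (-1.06) were lower in the 72 h effect. TAGLN (1.51) overlaps a gene on the opposite strand and RPL10P3 (-1.70) is a pseudogene that shares reads with paralogs, so both are uncertain. G2/M and mitosis genes had 0 called, median -0.13 (adjusted p = 0.143 with an estimated correlation). The count of 266 moved to 94 and 121 without NTC 48 h replicates 1 and 2, to 90 and 104 without NTC 72 h replicates 1 and 2, and to 139 without siER 72 h replicate 2.

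The siER effect at 48 h was set against each compound's effect to ask what distinguishes lowering of the transcript from a compound, with NTC and DMSO as separate controls. ESR1 differed by -2.31 from GDC-9545 and by -2.24 from GDC-0927. NPTN, which encodes a cell adhesion protein (ENSG00000156642, chromosome 15:73560014-73634134, minus strand), differed by -1.94 (0.08) with adjusted p = 5.78e-11 and by -1.88 (0.08), and it rose with the compounds themselves, by 0.21 and 0.15, where GREB1 fell further than with siER. Loss of the receptor protein was not separated from another action of the siRNA on NPTN. Some genes that every treatment lowered fell less with siER, such as IGSF1 by 2.60 and 2.10 and PDZK1 by 2.35 (0.40) and 1.78 (0.40) on the log2 scale. PDZK1 rested on few counts, 5 and 20 with GDC-9545, 16 and 10 with GDC-0927 and 22 and 34 with siER at 48 h. The call of PDZK1 against GDC-0927 was lost without GDC-0927 replicate 1 (1.84) and without siER 48 h replicate 2 (1.52). In total 1717 genes differed from GDC-9545, 911 higher and 806 lower, and 1586 from GDC-0927, 802 higher and 784 lower, with 329 and 235 differing 2-fold or more. The balance was not firm, since with no count filter 1507 were higher and 538 lower against GDC-9545 and 1588 and 539 against GDC-0927, and with the 72 h siRNA arms 665 and 172, and 518 and 169.

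Estrogen-induced genes were higher with siER than with GDC-9545 in 21 of 44 members and lower in 2, 25 and 3 adjusted over the list alone, median 0.39 (adjusted p = 0.000817 with an estimated correlation). Against GDC-0927 they were higher in 20 and lower in 4, 22 and 5 adjusted over the list alone, median 0.35 (adjusted p = 0.00229 with an estimated correlation). In the list GREB1 differed by 1.84 (0.12) from GDC-0927, and outside it CDH26 differed by 2.58 and MGP by 1.92 from GDC-9545, ATRNL1 by 1.83 from GDC-0927, and RAMP3 by 2.03 and 1.92. DNA replication and E2F targets were higher with siER than with GDC-9545 in 43 of 43, 43 adjusted over the list alone, median 0.92 (adjusted p = 3.53e-05 with an estimated correlation), and than with GDC-0927 in 41, 43 adjusted over the list alone, median 0.67 (adjusted p = 0.000147 with an estimated correlation). PRIM1 differed by 1.33 and 1.08. G2/M and mitosis genes were higher than with GDC-9545 in 31 of 32, 32 adjusted over the list alone, median 1.08 (adjusted p = 0.000277 with an estimated correlation), and than with GDC-0927 in 32, median 0.74 (adjusted p = 0.00119 with an estimated correlation). Estrogen-repressed genes were lower than with GDC-9545 in 6 of 15, 10 adjusted over the list alone, median -0.42 (adjusted p = 0.0343 with an estimated correlation), and than with GDC-0927 in 3, 6 adjusted over the list alone (adjusted p = 0.118 with an estimated correlation). With the 72 h siRNA arms they were lower in 1 of 15 against GDC-9545, median -0.25 (adjusted p = 0.0439 with an estimated correlation), and in 0 against GDC-0927 (adjusted p = 0.226 with an estimated correlation).

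Interferon-stimulated genes were lower with siER than with GDC-0927 in 19 of 25 members, 21 adjusted over the list alone, median -0.60 (adjusted p = 0.00409 with an estimated correlation), with IFIT3 at -0.90 and OAS2 at -0.84. Against GDC-9545 they were higher in 2 and lower in 1. NF-kB and inflammatory cytokine genes were lower with siER than with GDC-9545 in 6 of 10, 7 adjusted over the list alone, median -0.72 (adjusted p = 0.00794 with an estimated correlation), and than with GDC-0927 in 5, 7 adjusted over the list alone, median -0.67 (adjusted p = 0.008 with an estimated correlation), with RELB at -1.24 from GDC-9545. These genes differed between the controls, as described below, and with the 72 h siRNA arms 0 of 10 were called against either compound (adjusted p = 0.373 and 0.507 with an estimated correlation). CYP1A1 differed by -1.83 and -1.54, ACHE by -1.58 from GDC-9545, GABBR2, uncertain, by -1.62 from GDC-9545, and ACTG2 by -1.49 and TGM2, uncertain for an opposite-strand overlap, by -1.43 from GDC-0927. These genes stood higher in NTC at 48 h than with DMSO, and with the 72 h arms CYP1A1 (0.00 and 0.29), GABBR2 (-0.37), ACTG2 (-0.36) and TGM2 (-0.16) were not called, while ACHE was (-0.68). With the 72 h arms, an arm choice made after the data were seen, DNA replication and E2F targets were still higher with siER in 43 and 40 of 43 members, and interferon-stimulated genes were lower in 10 and 24 of 25.

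Counted as called genes, siER at 48 h and GDC-9545 changed 5523 genes in the same direction and 51 in opposite directions, against 812 up and 883 down expected, and these comparisons share no library. For siER at 72 h and GDC-9545 the numbers were 6438 and 13, and for GDC-0927 they were 5292 and 52 at 48 h and 6119 and 40 at 72 h. Of the 5523 shared genes 1041 differed in size, 1012 smaller and 29 larger with siER. Of the 6438 shared at 72 h 717 differed in size, 703 smaller and 14 larger with siER. The count of 1717 moved to 946 without DMSO replicate 2, to 1030 and 1010 without NTC 48 h replicates 1 and 2, and to 2765 without siER 48 h replicate 1. The count of 1586 moved to 720 without DMSO replicate 2, to 989 and 737 without GDC-0927 replicates 1 and 2, to 858 and 862 without NTC 48 h replicates 1 and 2, and to 2553 and 1053 without siER 48 h replicates 1 and 2.

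NTC at 48 h was compared with mock DMSO to ask how alike the controls are. They were not alike. CYP1A1 rose by 2.54 (0.15) from 1.6 to 9.26 CPM, and the retinoid genes STRA6, a retinol transporter gene, and DHRS3, which reduces retinal, rose by 2.24 and 1.97. RELB, an NF-kB subunit gene, rose by 1.47 from 4.64 to 12.6 CPM, and ESR1 fell by 0.54 with adjusted p = 1.4e-05. In total 6151 genes changed, 2849 up and 3302 down, and 519 changed 2-fold or more. The NTC arm differs from mock DMSO in the siRNA and in the vehicle, and the labels do not say that the arms were run side by side.

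NF-kB and inflammatory cytokine genes rose in 10 of 10 members in NTC at 48 h, 10 adjusted over the list alone, median 1.16 (adjusted p = 0.017 with an estimated correlation), with BIRC3 at 1.60, TNFAIP3 at 1.41 and IL6 at 2.53 from a low 0.103 to 0.536 CPM. NRF2 targets rose in 11 of 16, 12 adjusted over the list alone, median 0.34 (adjusted p = 0.0218 with an estimated correlation), with HMOX1 at 1.15 and the cystine transporter gene SLC7A11 at 1.09. G2/M and mitosis genes fell in 20 of 32 and rose in 1, median -0.30 (adjusted p = 0.0675 with an estimated correlation). Estrogen-induced genes fell in 21 of 44 and rose in 6, median -0.18 (adjusted p = 0.0675 with an estimated correlation), with PDZK1 at -1.03 and TFF1 at 0.86. Interferon-stimulated genes rose in 6 of 25 and fell in 7, with a median of 0.05 and a mean of -0.03, so the signs differed. KRT81 (1.94) and TGM2 (1.84, uncertain) rose, NPY1R (-1.68), MGP (-1.46) and PPP1R3C (-1.34) fell, and RPL39 (-1.36) and BCAS2P2 (-1.34) fell but share reads with paralogs. The count of 6151 moved to 2635 without DMSO replicate 2 and to 3805 and 3559 without NTC 48 h replicates 1 and 2.

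NTC at 72 h was compared with NTC at 48 h, which held 6588 changed genes, 3519 up and 3069 down, 523 of them 2-fold or more. This comparison and the one before it share the NTC 48 h libraries with opposite sign, so opposite changes arise in part by construction. CYP1A1 (-2.96), STRA6 (-2.34), DHRS3 (-1.79), TGM2 (-1.73, uncertain) and ACTG2 (-1.68) fell, and NPY1R (1.63), FANCB (1.4) and MGP (1.39) rose. RPL39 (1.45) and BCAS2P2 (1.31) rose with the limit given above, and ESR1 rose by 0.44. NF-kB and inflammatory cytokine genes fell in 10 of 10, median -1.14 (adjusted p = 0.00394 with an estimated correlation), NRF2 targets fell in 12 of 16, median -0.35 (adjusted p = 0.0203 with an estimated correlation), and basal epithelial markers fell in 5 of 14 and rose in 1 (adjusted p = 0.0457 with an estimated correlation). The count of 6588 moved to 4079 and 3916 without NTC 48 h replicates 1 and 2 and to 4364 and 3819 without NTC 72 h replicates 1 and 2. NTC at 72 h against mock DMSO, added after the data were seen, gave 0 changed genes with edgeR, where 258 genes had an unadjusted p under 0.05. DESeq2 and limma-voom also called 0 there, with 82 and 298 genes at an unadjusted p under 0.05. Each of these numbers is below 0.05 of the 18918 tested genes, the share expected with no change. The tests were therefore strict for these groups, and 0 calls do not show that the controls were equal. All groups shared 1 model, though duplicates were not equally alike. A chi-square between the counts of duplicates, per gene, was 18.93 with GDC-9545 and 16.31 with siER at 48 h. The same measure, which also grows with depth, was 5.8 with DMSO, 3.14 with NTC at 48 h and 3.38 with NTC at 72 h. Tests of GDC-9545 and of siER at 48 h may thus be less strict.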

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

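Apart from the differences between groups and leaving out 1 library, the tests in this part (the lasting effect of NTC, GC content, thinning, the set-up of the 48 h siRNA arms and of the GDC-0927 libraries, and those on NPTN) were chosen only after the result was seen, though the bounds for GC content, thinning and the shared stretch were set before their values were read.

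Differences between groups were called for the siER effect at 72 h against 48 h in 266 genes, and for the siER effect at 48 h against the effect of GDC-9545 in 1717 genes and of GDC-0927 in 1586 genes. The difference of siER effects between the times was 0.57 for ESR1, 0.79 for PGR, 1.29 for GREB1, 1.51 for PDZK1 and 0.77 for CXCL12, each less lowered at 72 h. The call of PDZK1 was lost without siER 48 h replicate 1 (1.30) or siER 72 h replicate 2 (1.39). The lists that differed between the times did so at adjusted p-values with an estimated correlation of 0.00532 for estrogen-induced genes, 0.00604 for interferon-stimulated genes, 0.0055 for NF-kB and inflammatory cytokines, 0.0383 for cholesterol synthesis and uptake and 0.00607 for aryl hydrocarbon receptor targets. For the NF-kB, aryl hydrocarbon receptor, cholesterol and estrogen-induced lists the NTC control itself moved between the times, as given above. The count of 266 moved to 94 and 121 without NTC 48 h replicates 1 and 2, to 90 and 104 without NTC 72 h replicates 1 and 2, and to 139 without siER 72 h replicate 2.

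NTC at 48 h differed from mock DMSO in 6151 genes, and this control enters every siER value at 48 h. The genes changed 2-fold or more at 48 h did not keep that change, with a median of 0.11 at 72 h against 1.29 at 48 h. These genes were picked for their change at 48 h, the bound was set after the result was seen, and mock DMSO is labelled 48 h. A weaker lasting effect of the siRNA, or one in other genes, is therefore not excluded. GC content and unequal depth are each excluded as the whole cause, with 3829 genes kept in the same direction after a GC trend was removed and 5430 after thinning. Still, 2322 calls were lost with the GC trend, and the fold changes of NTC at 48 h against DMSO correlated with GC content across genes at r = 0.58. The change from 48 h to 72 h correlated across genes at r = 0.82 between the NTC and siER arms, which share no library. A set-up difference of the 48 h siRNA libraries cannot be told apart from a passing response to nucleofection with siRNA.

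Interferon-stimulated genes lay lower with GDC-9545 than with GDC-0927. Without GDC-9545 replicates 1 and 2 and GDC-0927 replicates 1 and 2 the list's median was -0.66, -0.56, -0.61 and -0.58, so no single library carried the size of the difference. The bound set beforehand, at least 1 in 2 members called without each library, was missed without GDC-0927 replicate 1. The median was not the measure set beforehand, so a single library as the cause is not excluded by the planned test. GC content is excluded, with a median of -0.58 after the GC trend was removed. A set-up difference of the GDC-0927 libraries cannot be told apart from an action of the compound, since against DMSO the list had a median of 0.47 with GDC-0927, each compound has a single pair of libraries, and both GDC-0927 libraries share a mark in their column names that no other group holds.

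NPTN fell with siER and not with either compound. With GDC-9545 and GDC-0927 NPTN stood at 0.21 and 0.15 on the log2 scale, and the lower bound of the lower interval was 0.03. The difference of -1.94 from GDC-9545 held at adjusted p = 5.78e-11 over all genes. NPTN was picked for this difference, so loss of receptor function by a route the compounds share was bound to fail as the cause. These values are therefore no test of it. A long stretch shared with the ESR1 transcript is excluded, with a longest exact match of 12 bases, a length that 95.2% of 10332 genes reached or passed. NPTN recovered between the times by 0.58, like ESR1 at 0.57, which fits an action of the siRNA that fades, whether through ER or not. A short seed match of the siRNA was not tested, because the siRNA sequence is not in the sources used here, and loss of the receptor protein as opposed to its activity was not tested either.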

How the results depend on the processing

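The GC trend, thinning, leaving out the 48 h siRNA arms and exchanging control or time arms were chosen only after the result was seen. ESR1 kept its direction and its side of the threshold in all 48 values under other settings and all 24 without 1 library, as did the 19 leading list tests in 114 and 76 values. Named genes kept both in 1720 of 1728 values and, without 1 library, in 828 of 844. No named gene or list test reversed, and no scaling moved the median of all genes by over 0.1. Many named genes were picked as called and large in change, so their stability does not speak for all calls. With the GC trend removed, 62.3% of all calls for NTC at 48 h against DMSO were kept and 7 were opposite. For NTC at 72 h against 48 h 59.1% were kept and 18 were opposite. With 1 library left out, the lone library of its group is assumed to vary like the other groups. Small changes are limited by depth and n = 2, since 80% of genes changed 1.5-fold were recovered on simulated data and 54% for a difference of effects. These shares hold for genes with a mean over 1 CPM, and recovery among lower genes was not measured. The tests use counts, to which no pseudocount applies, and the prior count of 2 behind the components and correlations was not varied.

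For GDC-9545 against GDC-0927 the count of 193 became 373 with DESeq2, 406 with no filter, 353 with a replicate block, 32 with the compared groups alone and 887 with the GC trend removed. For the siER effect at 72 h minus 48 h 266 became 421 with the block and 1002 with the GC trend removed. Its balance turned from 195 higher and 71 lower to 148 and 213 with no filter, where the cause was not tested. For siER at 48 h minus GDC-9545 1717 became 1093 with the compared groups alone, 3285 with the GC trend removed and 837 (665 higher, 172 lower) with the 72 h arms. For siER at 48 h minus GDC-0927 1586 became 2787 with the GC trend removed and 687 (518 higher, 169 lower) with the 72 h arms. Near-even balances of 4914 up and 4832 down for GDC-9545, 3127 and 3456 for siER at 48 h and 3726 and 3530 for siER at 72 h tipped with no filter to 4539 and 5122, 3559 and 2954, and 3288 and 3851. They also tipped with the GC trend removed for siER at 48 h (3979 and 3918) and 72 h (4341 and 4449), with the strict filter for siER at 48 h (3318 and 3086) and with the compared groups alone for GDC-9545 (4406 and 4457). GDC-0927 tipped from 4641 and 4689 to 4684 and 4661 with RLE, among other settings, and siER minus GDC-0927 from 802 and 784 to 902 and 924 with DESeq2, so these near-even balances show no direction. With no filter NTC at 48 h against DMSO went from 2849 up and 3302 down to 2004 and 3936, and NTC at 72 h against 48 h from 3519 and 3069 to 4143 and 2001. The siER count at 48 h became 10485 with the 72 h NTC as control, and NTC against DMSO became 0 with the 72 h libraries. Fewer libraries estimate the spread when only the compared groups are fitted, the common dispersion was 0.00155 with the GC trend removed against 0.0037, and for the others the cause was not tested.

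Without 1 library the counts ran from 35 to 776 for GDC-9545 against GDC-0927, 90 to 266 for siER at 72 h minus 48 h, 946 to 2765 and 720 to 2553 for siER minus GDC-9545 and GDC-0927, 2635 to 5296 for NTC at 48 h against DMSO and 3819 to 4364 for NTC at 72 h against 48 h. Genes shared in direction that changed 2-fold or more in both numbered 1713 for both compounds, 782 and 1030 for GDC-9545 with siER at 48 h and 72 h, 738 and 936 for GDC-0927 with siER, and 650 for siER at both times, fewer because the minimum is stricter.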

Other observations

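The genes below were chosen only after the result was seen, and the values are given without an explanation. Besides ESR1, 4 genes were at least 1.5-fold lower with siER at both times and were called lower than with each compound in all 4 tests of the difference, whatever its size, and 0 were higher by the same rule. NPTN stood at -1.73 and -1.15 with siER at 48 h and 72 h, and B3GNT3 at -1.09 and -1.17. MAP3K3 stood at -0.88 and -0.85 and PFKM at -0.95 and -0.83, and both overlap another gene on the opposite strand and are uncertain. PFKM also fell with GDC-9545 (-0.42) and GDC-0927 (-0.29), only less than with siER. B3GNT3 (-0.14 and -0.15) and MAP3K3 (0.1 and 0.08) were not called with either compound. The longest exact stretch shared with ESR1 was 13 bases for B3GNT3, 16 for MAP3K3 and 12 for PFKM. A stretch of at least that length was found in 75.1%, 21.1% and 95.2% of 10332 genes.

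The sterol efflux genes ABCA1 and ABCG1 rose with both compounds, by 1.48 and 1.49 with GDC-9545 and by 2.16 and 2.01 with GDC-0927, and with siER, by 1.41 and 0.91 at 48 h and by 1.75 and 1.16 at 72 h. ABCA1 differed between the compounds by -0.67 with adjusted p = 0.00175 and ABCG1 by -0.52 with adjusted p = 0.000992. SCD, a fatty acid desaturase gene that shares reads with a pseudogene, fell to -0.85 with GDC-9545, fell less with GDC-0927 (-0.16), fell with siER at 48 h (-0.60) and 72 h (-0.86), and differed between the compounds by -0.69 (0.05) with adjusted p = 1.43e-06. The retinoid-induced gene CYP26A1 rose by 1.08 in NTC at 48 h against mock DMSO, beside STRA6 at 2.24 and DHRS3 at 1.97. APOBEC3B rose by 0.73 and 0.63 with siER at 48 h and 72 h and stood at -0.16 and 0.20 with GDC-9545 and GDC-0927, which were not called.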
